A study of Homo sapiens with 8 samples.

How the data were processed

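Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against ATF6 in memory regulatory T cells (Tregs) sorted from human blood. Per the labels, the subjects came from a group with autoimmune hepatitis (AIH), a group with autoimmune hepatitis arising de novo (dnAIH), a healthy control group (HC) and a liver-transplanted control group (LTC). The dnAIH and LTC groups both involve a transplant. Each group had 1 ATF6 library and 1 input library. The 4 ATF6 peak lists were analysed. The 4 input libraries entered no calculation here, and the design text names 5 subject groups, of which the fifth was not analysed here. Per the labels' protocols, the DNA was end-repaired, A-tailed, ligated to adapters and amplified by PCR, and the libraries were indexed.

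The submitters' processing notes name BWA, MACS2 and the build hg38, without versions, settings or roles. Each deposited list had the narrowPeak layout without a header line. In it the authors deposited a score per peak, which equalled the whole-number part of 10 times the −log10 q-value in the same row. The deposited fold enrichment, a ratio of the pileup at the summit to the local background in the MACS2 layout, was taken as the authors gave it. The −log10 p-value and the −log10 q-value of each peak were also deposited by the authors, and every q-value lay under 0.05. The start, the end and the summit offset in bp gave the position. Whether the input library served as background, whether the reads of several people were pooled, and what filtering followed the peak calling are not given in the sources used here. Fold enrichment was used to describe, rank or filter peaks within a list and not as a measure of binding strength between lists.

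From there, rows with the same interval and different summits were counted as 1 peak. Peaks on chromosome Y and at the XIST gene were left out throughout, and peaks on unplaced or alternative sequences were left out wherever a distance to a gene was needed. Gene positions came from a RefSeq table of the GRCh38.p14 assembly, with 58419 genes on the chromosomes used, of which 19821 were protein-coding. Genes on scaffolds, 755 in all, were left out. The table gave no strand, so a transcription start could not be told from the other end of a gene. The promoter class planned before the data were examined became peaks within 1000 bp of either end of a protein-coding gene, called gene-end peaks. No genome sequence was used here, so the planned search for ATF6 elements and the repeat-masked share were not run. Assembly gaps were not avoided in the shuffles for the same reason.

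A pair of lists shared a peak where intervals overlapped by at least 1 bp, and the share is given of the shorter list. Overlaps were set beside 1000 shuffles of the shorter list within its chromosomes, between the first and the last annotated gene. A further 200 shuffles kept the class of distance to the nearest gene end, and 200 kept the 1 Mb window of each peak. Overlapping peaks of the 4 lists were merged into regions, and each region was assigned to the set of lists that held it. The 18 gene lists were fixed before the data were examined. A list's number of members with a gene-end peak was compared with 10000 random lists of protein-coding genes matched on 10 classes of gene length, in place of the planned match on promoter GC content. Peaks over 500 kb from any protein-coding gene were called distant, a class chosen after seeing the data.

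The files give no read totals, so the depth in reads is unknown. A background was estimated from each row with a −log10 p-value under 100, and the lowest in a list was taken as its relative background level. It was assumed that fold equals (pileup + 1) divided by (background + 1) and that the p-value is the Poisson upper tail. Under that assumption a whole-number pileup matched the printed p-value within 0.005 in 99.4% of 4060 AIH rows, 99.2% of 1081 dnAIH rows, 99.7% of 3472 HC rows and 99.2% of 1070 LTC rows. With p-values exchanged between rows, 1.75 to 4.75% of 400 rows per list matched. In simulated peaks the pileup was recovered in 100% of 558 rows, and simulated lists with 400 planted overlaps gave 400. The simulated values were made with the same formulas, so both results check the calculation and not the assumption.

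Always named were HSPA5, HSP90B1, HERPUD1, XBP1, DDIT3, ATF6, STAT3, IL17A and FOXP3. The rule then took members of the fixed lists with a gene-end peak (up to 30), the 5 gene-end peaks of highest fold in each list and up to 10 regions held by all 4 lists by median fold. It also took up to 10 gene-end regions held by AIH and dnAIH alone, by HC and LTC alone, and by each list alone. Genes named outside this rule are marked as chosen after their values were seen. A single named region in the part of chromosome X that is shared with chromosome Y is not reported here, nor is a further gene of the rule.

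No group had replicates, so there was no replicate check, no p-value between groups was computed, and differences between lists describe these libraries. Shares carry Wilson 95% intervals, which cover counting error only. Alternatives set before the data were examined were a −log10 q-value of at least 5, a fold of at least 5, other windows around gene ends, all annotated genes, other overlap rules and other joining distances. Further alternatives were the 1000 strongest peaks of each list, the summit in place of the interval, autosomes alone and unmatched random lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.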

Results

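ATF6 is a membrane-bound transcription factor of the endoplasmic reticulum that is cleaved and moves to the nucleus when unfolded proteins accumulate there. Its chromatin occupancy was profiled in memory Tregs from the blood of AIH, dnAIH, HC and LTC subjects, with 1 ATF6 library per group. The question, as the series title puts it in other words, concerns an unfolded protein response linked to a retroviral envelope protein in autoimmune liver disease. The lists held 3892 peaks in AIH, 1020 in dnAIH, 3242 in HC and 1000 in LTC, with 4204, 1210, 3559 and 1175 summits. Positions are given on hg38. There are no replicates, so every difference below compares 4 libraries and not 4 conditions.

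The first comparison concerned the unfolded protein response genes that ATF6 is known to act on. None of the 25 chaperone and folding genes, which include HSPA5 (BiP) and HSP90B1 (GRP94), had a gene-end peak in any of the 4 lists. The 22 genes of endoplasmic reticulum-associated degradation had none either. Of the 31 sensors and transcription factors of the response, CREB3L3, a liver-enriched membrane-bound transcription factor, had a gene-end peak in HC (fold 5.02) and LTC (fold 5.11) on chromosome 19 at 4172383 to 4172680. Neither autoimmune list held it. The peak lay near the higher-numbered end of the gene, which spans 4153631 to 4173054. Without strand it is not shown to be at the promoter. Among length-matched random lists, 6.49% held at least 1 gene with a gene-end peak in HC and 5.80% in LTC. With a −log10 q-value of at least 5, the number fell to 0 in both lists. Over the 77 measured members of these 3 lists the numbers were thus 0 in AIH, 0 in dnAIH, 1 in HC and 1 in LTC. Random lists of these sizes had means of 0.0348 to 0.103 genes, so a count of 0 lies close to what chance gives here.

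The nearest peaks to the genes named in advance mostly lay far away. These distances were not compared with those of other genes, so they show no particular absence at the named genes. HSPA5 had its closest peak at 406 kb in AIH (fold 9.24) and dnAIH (fold 4.65), and at 5036 kb in HC and LTC. HSP90B1 had its closest at 1406 kb, in HC. For HERPUD1, a degradation factor induced by ATF6, the nearest peak lay 1076 kb away in all 4 lists. XBP1 had none closer than 989 kb, DDIT3 (CHOP) none closer than 1797 kb and ATF6 itself none closer than 306 kb. Of the T cell genes, STAT3 had its closest peak at 845 kb and IL17A at 805 kb. FOXP3, the factor that defines Tregs, had a peak at 64.9 kb in HC (fold 5.02) and at 1869 kb or more in the other lists. That HC peak is the one beside GAGE12J, a tandem-copy gene, so the placement of its reads is uncertain.

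The other lists fixed in advance gave a similar picture for T cell genes. No gene-end peak was present in any of the 4 lists among the 30 Treg identity genes, the 24 Th17 genes, the 24 Th1 and inflammatory cytokine genes or the 12 Th2 genes. The same held for the 35 genes of T cell receptor signalling, the 24 of antigen presentation and HLA, and the 34 measured genes of the type I interferon response. It held as well for the 9 measured genes of endogenous retroviral envelopes, the 21 of cytosolic heat shock and the 30 of cytosolic ribosomal proteins. Markers of other cells that a sort could hold had none: 14 for B cells, 16 for monocytes and macrophages, 15 for NK and CD8 T cells and 20 for hepatocytes. Peaks inside the gene occurred in 4 of these 306 genes in AIH, 1 in dnAIH, 2 in HC and 2 in LTC. Length-matched random sets had means of 4.197, 3.03, 3.68 and 2.69, and 60.8%, 95.3%, 88.9% and 75.9% of them had as many, so these counts did not exceed chance. The genes with internal peaks are named here after their values were seen. NFATC1, a calcineurin-dependent factor of T cell activation, had an internal peak in all 4 lists, with folds of 9.86 in AIH, 11.3 in dnAIH, 5.57 in HC and 8.30 in LTC. SAMHD1, a restriction factor for retroviruses, had an internal peak in AIH (9.24), HC (4.74) and LTC (9.57). CD5 and REL had an internal peak in AIH alone, both at a fold of 6.16.

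Core histone genes were the exception among the 18 lists. Of 18 members, 5 had a gene-end peak in AIH, 5 in dnAIH, 3 in HC and 3 in LTC. As many were found in 0% of the 10000 random lists for AIH, 0% for dnAIH, 0.04% for HC and 0.02% for LTC. Random lists scatter over the genome, whereas histone genes are neighbours that share peaks: the members rested on 3 distinct peaks in AIH, 3 in dnAIH, 2 in HC and 2 in LTC. With the list shifted 10000 times along the gene order, which keeps neighbours together, as many were found in 0.03%, 0.03%, 0.12% and 0.13% of shifts. The shift was chosen after seeing the data. H3C10 had a peak in all 4 lists, with folds of 14.5 in AIH, 18.7 in dnAIH, 7.18 in HC and 9.32 in LTC. H2AC6 and H2BC4, which lie head to head, shared a peak in AIH (17.7), dnAIH (16.7) and HC (8.82). H3C1 and H4C1 shared a peak in AIH (5.63), dnAIH (5.84) and LTC (6.38). Among the 79 annotated histone genes, 23 had a gene-end peak in AIH, 21 in dnAIH, 15 in HC and 21 in LTC. They made up 35.4%, 51.2%, 35.7% and 55.3% of all genes with such a peak in these lists. Histone genes are clustered near-identical copies, so the assignment of reads between them is uncertain.

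Over all protein-coding genes, few gene ends carried a peak. The number of genes with a gene-end peak was 65 in AIH, 41 in dnAIH, 42 in HC and 38 in LTC, of 19821. Altogether 84 genes had such a peak in at least 1 list, 24 of them in all 4. AIH alone accounted for 24 genes, HC alone for 9, LTC alone for 3 and dnAIH alone for 2. Gene-end peaks were 1.504% of the AIH peaks on chromosomes (57 peaks, 95% interval 1.16 to 1.94%) and 1.23% of the HC peaks (38 peaks, 0.896 to 1.68%). Shuffled peaks gave means of 2.67% and 2.73%, so the observed shares lay below every shuffle in both lists (lowest 1.90% and 1.84%). Distant peaks cannot be gene-end peaks. They made up 65.7% of AIH and 60.01% of HC peaks on chromosomes, against means of 12.4% and 12.3% in shuffled peaks. The low shares therefore do not show that the other AIH and HC peaks avoid gene ends. In dnAIH the share was 3.47% (34 peaks, 2.49 to 4.80%) and in LTC 3.33% (32 peaks, 2.37 to 4.66%). Those lay inside the shuffled range, which had means of 3.11% and 3.09%. Among the 1000 strongest peaks of each list, the share was 3.01% in AIH and 2.13% in HC. Within 5000 bp of a gene end lay 4.88% of AIH, 11.7% of dnAIH, 4.88% of HC and 11.02% of LTC peaks, against shuffled means of 10.4%, 11.5%, 10.6% and 11.6%.

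GOLM2, COL6A1 and SNX16 had peaks among the 5 strongest gene-end peaks of each list. The peak beside GOLM2, which encodes a Golgi membrane protein, ranked first among the gene-end peaks of each list. It lay on chromosome 15 at 44288396 to 44288599. Its fold was 270 in AIH, 226 in dnAIH, 112 in HC and 225 in LTC. COL6A1, a collagen VI chain, had folds of 95.5, 120, 69.1 and 90.0 on chromosome 21 at 45980522 to 45981115. SNX16, an endosomal sorting nexin, had folds of 75.8, 64.3, 27.5 and 49.9, on chromosome 8 at 81842339 to 81842580. USB1, an exonuclease that trims U6 RNA, had folds of 29.6, 31.2, 16.7 and 26.2. The homeobox gene MEIS3 had folds of 29.6, 30.6, 16.2 and 19.8. SHCBP1L and the histone genes H4C14, H4C15 and H2BC13 with H2AC13 completed the named gene-end regions that all 4 lists held. H3C14, among the 5 strongest gene-end peaks in HC at a fold of 19.1, was also present in AIH (10.5) and LTC (7.95). WEE2, a kinase known from oocytes, had a peak in AIH (54.2) and HC (37.4) alone.

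**Figure D1:**
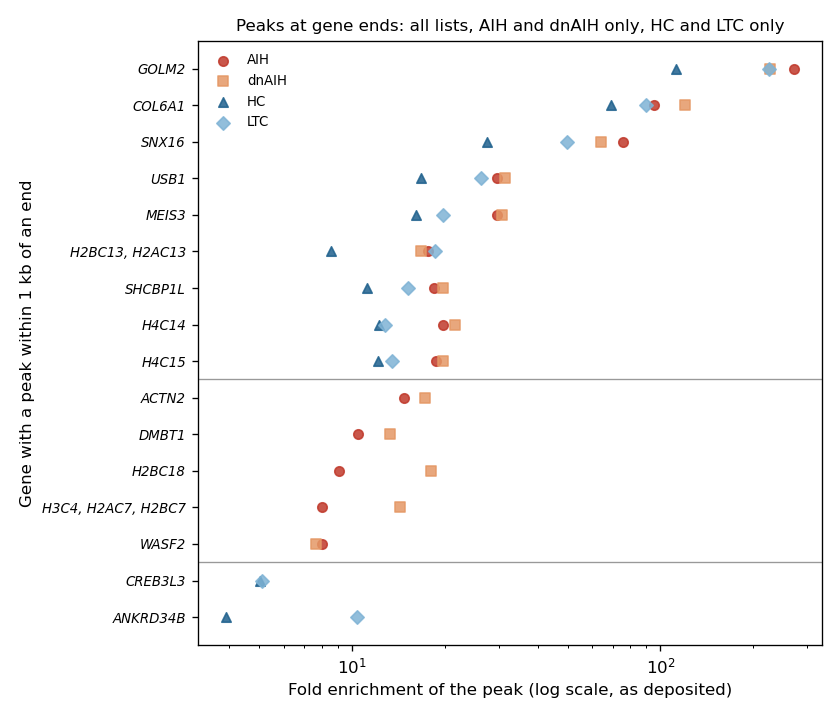
Deposited fold enrichment (log axis) of peaks within 1000 bp of a protein-coding gene end, with 1 point per ATF6 library. The upper block shows regions held by all 4 lists, led by GOLM2 at 112 to 270, the middle block regions held by AIH and dnAIH alone, and the lower block regions held by HC and LTC alone.

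Sites of highest fold lay mostly away from gene ends and recurred in the 4 lists. The first was on chromosome 7 at 157461262 to 157461691, 43.8 kb from the nearest protein-coding gene, with folds of 1998 in AIH, 2085 in dnAIH, 1338 in HC and 1433 in LTC. The second lay inside ANAPC7, a subunit of the anaphase-promoting complex, on chromosome 12 at 110387210 to 110387437, with folds of 1127, 1079, 476 and 895. Another, on chromosome 12 at 118757662 to 118757883, lay 224 kb from a protein-coding gene and had folds of 572, 562, 370 and 514. SLC39A14, a zinc transporter, held an internal site on chromosome 8 at 22396382 to 22396604 with folds of 508, 470, 302 and 409. ZNF664-RFLNA on chromosome 12 and KIAA1671 on chromosome 22 each held an internal site with folds of 223 to 478. The other 4 of the 10 strongest lay outside genes on chromosomes 11, 14, 22 and 10. In all, 572 regions were held by every list, and 87 of the 100 strongest AIH peaks, 97 in dnAIH, 89 in HC and 99 in LTC fell in them. Across these 572 regions the folds of list pairs had Spearman rho between 0.89 and 0.93, where regions are not independent replicates. The ends of the 100 strongest regions differed between lists by a median of 7 bp at the start and 5 bp at the end.

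The first case-control pair, AIH against HC, shared 1424 of the 3242 HC peaks, which is 43.9% (42.2 to 45.6%). Shuffling within chromosomes gave 0.0664%, and shuffling within the 1 Mb window of each peak gave 2.71%, at most 3.56%. AIH had 650 more peaks than HC. The second pair, dnAIH against LTC, shared 675 of the 1000 LTC peaks, which is 67.5% (64.5 to 70.3%), against 0.0288% and 0.316% in the same shuffles. dnAIH had 20 more peaks than LTC, and both of these groups involve a transplant. The autoimmune lists AIH and dnAIH shared 80.6% of the dnAIH peaks (78.0 to 82.9%) and the control lists HC and LTC 71.1% of the LTC peaks (68.2 to 73.8%). Pairs that cross disease and transplantation gave 79.7% for AIH with LTC (77.1 to 82.1%) and 70.5% for dnAIH with HC (67.6 to 73.2%). The shares of dnAIH and LTC peaks found in AIH had overlapping intervals. With the 1000 strongest peaks of each list, AIH and dnAIH shared 52.2%, HC and LTC 45.6%, AIH and HC 63.1% and dnAIH and LTC 67.2%.

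Regions held by the autoimmune lists and no control were few. Of 5974 merged regions, 82 were held by AIH and dnAIH alone, beside 67 by AIH and LTC, 35 by HC and LTC, 31 by dnAIH and HC and 21 by dnAIH and LTC. AIH and HC alone held 644. With the 1000 strongest peaks of each list, AIH and dnAIH alone held 26 regions, AIH and LTC 25, dnAIH and HC 21 and HC and LTC 14. Under the same cut dnAIH and LTC alone held 184 and AIH and HC alone 172. The cut shortens AIH and HC most, so regions counted for dnAIH and LTC alone can have a peak in the full AIH or HC list. Only 5 of the 82 regions lay at gene ends. They were at ACTN2, a muscle alpha-actinin (folds 14.8 in AIH and 17.3 in dnAIH), at DMBT1, a mucosal scavenger receptor (10.5 and 13.3), and at WASF2, an actin regulator (8.01 and 7.65). The others were at the histone genes H2BC18 (9.08 and 18.0) and H3C4 with H2AC7 and H2BC7 (8.01 and 14.3). H2BC18 also had a gene-end peak in LTC at another position. HC and LTC alone held 2 gene-end regions, at CREB3L3 and at ANKRD34B (3.90 in HC and 10.4 in LTC).

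**Figure D2:**
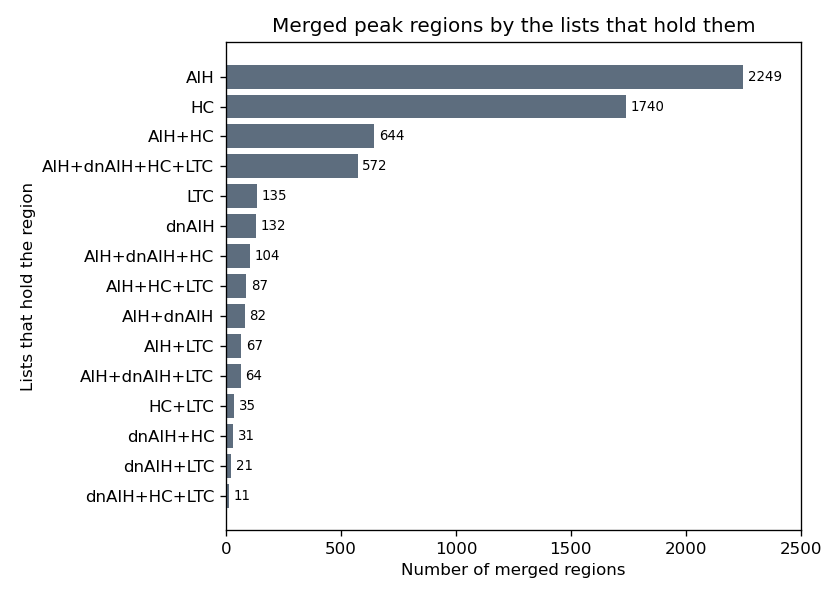
Number of merged peak regions (horizontal axis) for each set of lists that holds them (vertical axis), over 5974 regions. AIH alone (2249) and HC alone (1740) are the longest bars, 572 regions are in all 4 lists, and AIH with dnAIH alone has 82.

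Gene-end regions held by a single list numbered 25 in AIH, 2 in dnAIH, 10 in HC and 3 in LTC. Those of AIH with a fold of at least 6.78 are named here. The first was 0.344 kb from an end of GSTA4 (104), where the annotated small nuclear RNA gene RN7SK covers the peak. Next were CSH1, a placental lactogen gene, with peaks of 58.2 and 12.1, MDGA1 (30.8), the gastric proton pump gene ATP4A (11.1), PAPPA (10.9), CSH2 (10.3) and KLK14 (8.63). The AIH peak beside CCDC107 (8.01) lies in RMRP, the RNA of RNase MRP, and CHRNE and PSG1 had 6.78. PSG1, RN7SK and RMRP are outside the naming rule and were chosen after their values were seen. In dnAIH there were MMS22L, a replication repair gene (5.57), and EMC10, of the endoplasmic reticulum membrane complex (5.32). HC alone held regions at TAF11L8, USP17L11, USP17L17, USP17L12, LATS1, GAGE12J and 4 uncharacterised loci, all with folds of 5.67 or less. LTC alone held regions at ATAD3C (9.63) and at the histone genes H3C8 (6.87) and H4C9 (4.35). The USP17L, TAF11L and GAGE genes are tandem copies, and reads may be split between them.

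Most of the length of the AIH and HC lists came from peaks far from genes. In AIH 2491 peaks, 65.7% of those on chromosomes (64.2 to 67.2%), lay over 500 kb from any protein-coding gene, and in HC 1856, or 60.01% (58.3 to 61.7%). The corresponding values were 205 peaks, or 20.9% (18.5 to 23.6%), in dnAIH and 272, or 28.3% (25.5 to 31.2%), in LTC. Shuffled peaks gave 11.6 to 12.4%. Among the 1000 strongest peaks of each list the shares were 48.5% in AIH, 55.5% in HC, 20.6% in dnAIH and 28.3% in LTC, so the order of AIH and HC turned. Distant peaks had median folds of 4.78 in AIH, 4.70 in dnAIH, 4.67 in HC and 4.47 in LTC, and the other peaks on chromosomes had 7.38, 11.3, 5.57 and 10.4. Of the difference between the mean of AIH and HC and the mean of dnAIH and LTC, 78.3% was in distant peaks. Their mean number was 9.11 times higher in AIH and HC, against 1.73 times for other peaks on chromosomes.

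**Figure D3:**
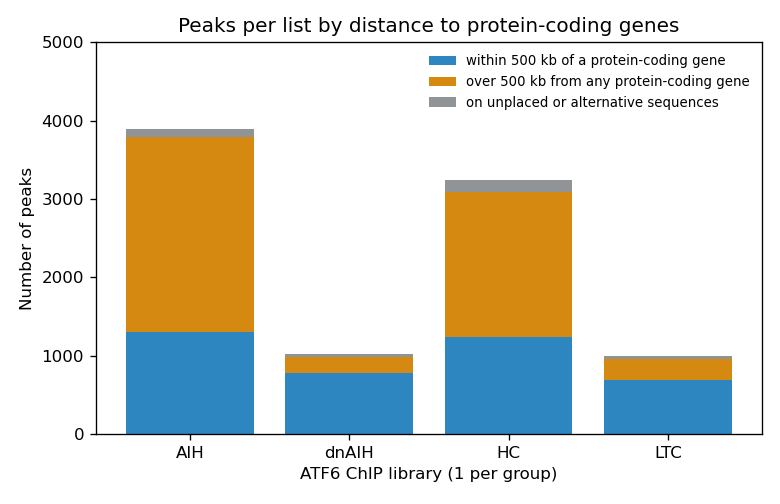
Number of peaks per ATF6 library, split by distance to the nearest protein-coding gene. Peaks over 500 kb from a gene number 2491 in AIH, 205 in dnAIH, 1856 in HC and 272 in LTC, while those nearer number 1299, 776, 1237 and 690.

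The distant peaks were concentrated in a small number of windows, named here after their values were seen. The 20 windows of 1 Mb with most peaks held 44.7% of the AIH peaks on chromosomes, 15.8% in dnAIH, 47.4% in HC and 22.8% in LTC, and 17 of the 20 held no protein-coding gene. The window on chromosome 13 from 17000001 to 18000000 had 286 peaks in AIH, 23 in dnAIH, 183 in HC and 52 in LTC. The window on chromosome 1 from 124000001 to 125000000 had 164, 23, 224 and 24. AIH exceeded HC in the first window and HC exceeded AIH in the second. Both windows belong to centromeric parts of their chromosomes, which consist of tandem satellite repeats. The window on chromosome 10 from 40000001 to 41000000 had 108, 13, 107 and 11.

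**Figure D4:**
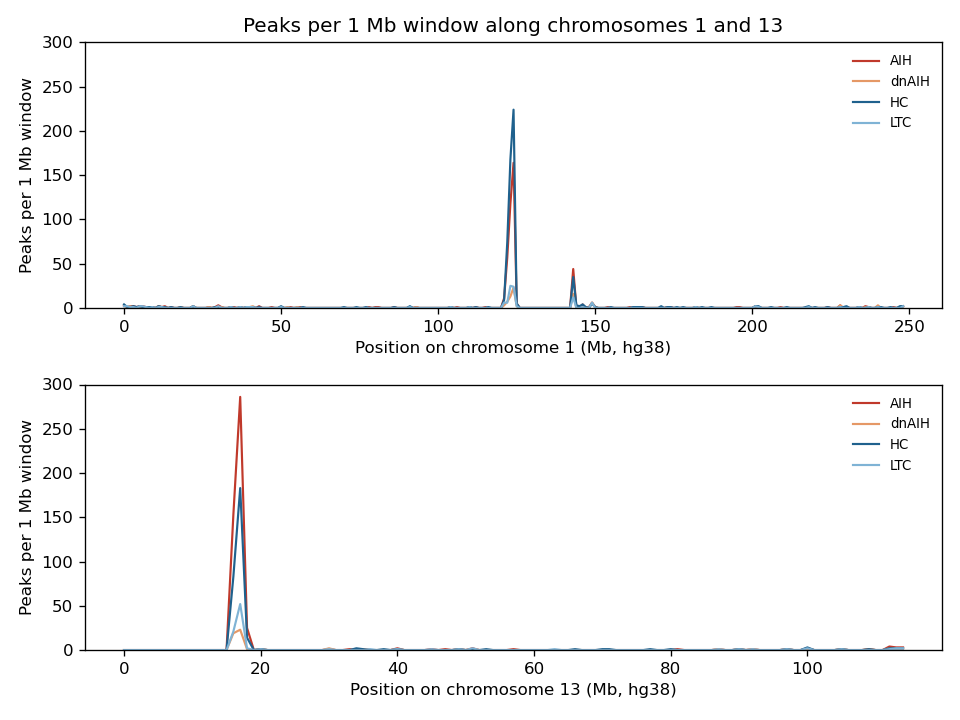
Peaks per 1 Mb window (vertical axis) along chromosomes 1 and 13 (horizontal axis, Mb), with 1 line per ATF6 library. The highest windows reach 224 peaks on chromosome 1, in HC, and 286 on chromosome 13, in AIH. The smaller cluster at 143 Mb on chromosome 1 has 44 peaks in AIH, 16 in dnAIH, 35 in HC and 12 in LTC.

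The lowest background level recovered from the deposited fold and p-values was 0.623 reads in AIH, 0.505 in dnAIH, 0.794 in HC and 0.567 in LTC. Relative to dnAIH this lowest level was 1.23 in AIH, 1.57 in HC and 1.12 in LTC. The median local background of the rows was 1.53 in AIH, 0.505 in dnAIH, 1.69 in HC and 0.649 in LTC. Of the solved rows, 23.1% in AIH, 55.5% in dnAIH, 32.4% in HC and 45.9% in LTC lay at the lowest level. The smallest peak widths were 165 bp in AIH, 162 bp in HC, 186 bp in dnAIH and 191 bp in LTC. Median folds over all peaks were 5.10 in AIH, 8.69 in dnAIH, 4.90 in HC and 8.28 in LTC. The lowest pileup that made a peak was 6 reads in each list, so a gene without a peak had no occupancy detectable at this depth, which does not show that ATF6 was absent.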

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

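All comparisons and tests in this part were chosen after the peak lists had been examined. Differences that ran in opposite directions in the case-control pairs are given first. The share of peaks over 500 kb from a protein-coding gene was 5.72 percentage points higher in AIH than in HC (65.7 against 60.01%), while the dnAIH minus LTC difference was -7.38 percentage points (20.9 against 28.3%). The share of peaks inside a protein-coding gene gave -1.20 percentage points for AIH minus HC (12.9 against 14.1%) and 4.30 for dnAIH minus LTC (35.1 against 30.8%). With 1 library per group the difference was not tested. The directions were not opposite among the 1000 strongest peaks of each list, a selection that changes list length and peak strength together: AIH minus HC was then -6.95 percentage points for the distant share and 3.57 for the share inside genes. dnAIH minus LTC was -7.71 and 4.33. Why AIH and HC changed order was not tested.

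The AIH and HC lists were each at least 3.18 times as long as the dnAIH and LTC lists, mostly through peaks over 500 kb from any protein-coding gene. Sequencing depth of the ATF6 libraries alone is argued against, as far as the lowest recovered background of each list measures depth. With pileups thinned to the dnAIH depth and the stricter p-value threshold of the short lists, at least 3117 AIH and 2096 HC peaks were left. The fewest left were 2.05 times the longer of the short lists (counting interval 1.91 to 2.22). The thinning treated reads as independent, and the depth of any input library used as background was not covered. A difference in library batch or fragment size stays open, since the smallest peak widths of the pairs were separated by 21 bp. It cannot be told apart from liver transplantation, because the dnAIH and LTC subjects, in the groups with the short lists, are also those whose group involves a transplant.

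The strongest sites recurred in all 4 lists with nearly the same ends. Whether this signal was placed without regard to genes stays open. Leaving out histone genes, 2.57% of the 544 regions on chromosomes held by all 4 lists lay at a gene end. That is within the 1.29 to 6.07% of shuffled regions. With histone genes the share was 4.04%, also within that range. These shares cannot decide the question, because binding away from gene ends would give low shares too. They also cover all 544 regions and not the strongest sites alone. Input libraries were not used here, so whether the same sites are enriched without the antibody stays open, and no biological explanation was tested.

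AIH alone had strong peaks at genes of abundant RNAs: RN7SL2 (fold 112), RN7SK (104), RN7SL1 (71.9) and RMRP (8.01), and at the placental genes CSH1 (58.2), PAPPA (10.9), CSH2 (10.3) and PSG1 (6.78), all noted before the tests. General occupancy of RNA polymerase III genes is argued against for the tRNA genes, of which 0 of 429 had an AIH peak. Without the RNA genes above, 0.216% of 463 polymerase III genes (0.0381 to 1.21%) had one, namely the 5S gene RNA5S4 (fold 15.6). The 34 of these that are not tRNA genes are too few to decide. With the RNA genes above, 5 of 38 polymerase III genes other than tRNA genes had a peak in AIH, and 0 in dnAIH, HC and LTC. Occupancy limited to a few polymerase III genes was not tested, and reads carried over from a placental RNA library stay open. Of 45 placental genes not noted before, 1 (PSG4, fold 6.78) had an AIH peak, against a mean of 0.252 in random lists, of which 22.3% had as many. PSG4 and PSG1 are close paralogs, so these may be the same reads, and a sort for Tregs would remove placental cells but not DNA or RNA added later.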

How the results depend on the processing

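No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Leaving out replicates was not possible either. The searches for ATF6 elements and the repeat-masked shares were not run for want of a genome sequence. Restricting to peaks within 500 kb of genes, counting summits, shuffling within 1 Mb windows, leaving out AIH, shifting the histone list and taking the 1000 strongest peaks for the distant and in-gene shares were chosen after seeing the data. Of the planned comparisons 85 stayed and 59 moved. Of the added ones 16 stayed, 14 moved and 2 reversed. Counts were taken to stay within 1.5 times the count, shares within their counting interval and chance overlaps within the spread of the shuffles. The median folds that stayed lay within the quartiles of their list. With the 1000 strongest peaks, AIH minus HC turned from 5.72 to -6.95 percentage points for the distant share and from -1.20 to 3.57 for the share inside genes. Members of the unfolded protein response lists stayed at 0 in AIH and dnAIH under each alternative run. Depth limits all counts. Where a stricter threshold, fewer peaks or another window gave another count, its construction explains that; for the other changes the cause was not tested.

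With a −log10 q-value of at least 5, AIH had 2240 peaks and HC 1756. With a fold of at least 5 they had 2006 and 1544, and within 500 kb of a gene 1299 and 1237. Gene-end shares with a 500 bp window were 0.976% in AIH, 2.34% in dnAIH and 0.841% in HC. With 5000 bp they were 4.88% in AIH, 11.7% in dnAIH, 4.88% in HC and 11.02% in LTC. With all annotated genes they were 4.06, 8.97, 4.56 and 8.00%. The q-value threshold gave 2.16% in AIH, and the 1000 strongest peaks gave 3.01% in AIH and 2.13% in HC.

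Shared peaks of AIH with HC, dnAIH with LTC, AIH with dnAIH and HC with LTC were 39.6, 63.6, 75.6 and 65.4% with 50% of both peaks overlapping. With summits within 100 bp they were 38.3, 59.1, 73.1 and 62.1%, and within 500 kb of a gene 56.7, 81.3, 84.0 and 75.9%. The q-value threshold gave 57.1% for AIH with HC and 72.2% for dnAIH with LTC. The 1000 strongest peaks gave 63.1% for AIH with HC, 52.2% for AIH with dnAIH and 45.6% for HC with LTC. Without scaffolds and the strongest 1%, AIH with dnAIH shared 77.9% and HC with LTC 68.1%. Chance overlap within 1 Mb windows was 2.71, 0.316, 1.19 and 1.48%, and within gene-distance classes 0.249% for AIH with HC.

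Among the 1000 strongest peaks, 375 regions were held by all lists, 26 by AIH and dnAIH, 14 by HC and LTC, 172 by AIH and HC, 184 by dnAIH and LTC and 25 by AIH and LTC. The q-value threshold left 18 for HC and LTC and 390 for AIH and HC. Within 500 kb of a gene there were 11 for HC and LTC, 129 for AIH and HC, 25 for AIH and LTC and 14 for dnAIH and HC. Genes with a gene-end peak numbered 42 in AIH and 27 in dnAIH with 500 bp, and 215, 143, 169 and 137 in AIH, dnAIH, HC and LTC with 5000 bp. The 1000 strongest peaks gave 32 genes in AIH and 22 in HC. Core histone genes fell to 3 in AIH with the 1000 strongest peaks and to 3 in dnAIH with the q-value threshold. The unfolded protein response count fell to 0 in HC under both settings and to 0 in LTC with the q-value threshold. Median folds in regions held by all lists were 13.6 in AIH and 10.0 in HC, and at gene ends 10.3 and 7.42. They were also higher in dnAIH (15.3 and 15.6) and LTC (12.8 and 10.0) than over all peaks, though within the quartiles of those lists.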

Other observations

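Genes of structural RNAs carried peaks that the report's gene lists do not cover, and they were chosen after their values were seen. In the 3 annotated ribosomal DNA repeats on chromosome 21, the strongest peak of each had a mean fold of 10.9 in AIH (9.83 to 12.9), 17.9 in dnAIH (15.5 to 19.4), 14.1 in HC (12.6 to 17.0) and 19.04 in LTC (16.7 to 23.7). These repeats are multicopy, and the ranges are over repeats in 1 library. The U2 small nuclear RNA cluster on chromosome 17 spans 43233790 to 43300231 with 13 annotated genes. In or beside it lay 13 peaks in AIH (median fold 15.7), 13 in HC (median fold 6.37) and 0 in dnAIH and LTC. Not every gene had its own peak. The strongest peak (48.1 in AIH, 24.5 in HC) lay outside the annotated genes, which reached 32.6 and 22.8 at RNU2-1. Over all 149 small nuclear RNA genes, 15 had a peak in AIH, 14 in HC and 0 in dnAIH and LTC. The nearest AIH and HC peak to STAT3, at 845 kb, belongs to this cluster, and the nearest AIH peak to IL17A is the one at RN7SK.

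Other strong peaks of a single list were also picked out by their values. HC alone had a peak inside CREBBP, a histone acetyltransferase, at a fold of 90.6 on chromosome 16 at 3849375 to 3849548, and inside DLGAP4 at 36.2. AIH alone had a peak inside CDH7 at 45.0, on chromosome 18 at 65781865 to 65782029. Its width was close to the smallest in the AIH list, 165 bp. Whether duplicate reads were removed is not given in the sources used here. A stack of copies of few fragments therefore cannot be told from occupancy at this peak, and the same may hold for other narrow peaks. The strongest peak found in dnAIH alone reached 12.6, inside SDK1, and that found in LTC alone 10.8, outside genes. In AIH alone a weak peak (fold 4.93) lay between AIRE, the regulator of self-antigen expression in the thymus, and PFKL. No hypothesis about these sites was tested.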
